A study of Mus musculus with 3 samples.

How the data were processed

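Single-cell RNA-seq was done on skin cells of AdipoqCre; mT/mG mice aged 7 weeks. In these mice a Cre recombinase driven by the adiponectin promoter recombines a membrane reporter, so that a cell and its descendants switch from tdTomato to eGFP. Per the labels, cells negative for CD45 (a leukocyte marker) and CD31 (an endothelial marker) were sorted and made into 10x Chromium libraries. There were 3 libraries. The wound group held 2 day 5 wound beds, replicate 9 (labelled female) and replicate 3 (labelled male), and the uninjured group held 1 library, replicate 5 (labelled male). The labels do not say how many mice went into a library, so the spread between libraries may be partly technical.

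The authors deposited raw UMI counts per gene and cell, made with kallisto, bustools and Seurat per the submitters' processing notes. Versions, the genome build, the annotation and any doublet filter are not given in the sources used here. The deposited matrix held 34699 gene symbols and 31015 cells, and no symbol was blank or duplicated. Each cell's counts summed to the total in the deposited cell table for all 31015 cells. The lowest total was 3001 UMIs per cell. The deposited cell table also gave raw eGFP and tdTomato UMI counts, a cluster number from 16 clusters and the percent of mitochondrial UMIs, which the authors expressed relative to the cell's total count. Reporter sequences were not among the genes of the matrix. A deposited table of normalized residuals for part of the genes was not used, because residuals cannot be summed per library. Of the symbols, 34166 were found in GENCODE vM21, which may not be the annotation the authors used, and which served here only to place 3 pseudogenes on chromosomes.

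Cells are not replicates, so raw counts were summed per library and cell class. Clusters carried no names. Each library's part of a cluster was named from 14 marker sets. The log2 ratio of a marker's CPM to the median cluster of that library was taken with a pseudocount of 10 CPM, and a class needed at least 3 markers at 4-fold or more. A part with no such class was named fibroblast unless its fibroblast markers lay low, a part with a close second class stayed unnamed, and no other class could lead among the cluster's 10 leading genes of over 50 CPM. Haemoglobin genes named no cluster. Those thresholds were set after looking at marker levels and were revised 1 time, before any test between groups was run. The fibroblast class took in clusters 0, 1, 2, 4, 5, 6, 7 and 9 in every library, and cluster 3 in the wound libraries. The 228 uninjured cells of cluster 3 carried keratinocyte markers and were placed with keratinocytes. Clusters 10, 13 and 14 stayed unnamed. No doublet caller was run.

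Differences were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. Wound against uninjured had 2 libraries against 1, which leaves 1 residual degree of freedom, and the lone uninjured library was assumed to vary like the wound libraries. Classes with at least 50 cells in every library were tested. Sex was not a covariate of these whole-library sums, and a split of cells by sex genes was added later with sex as a term. Cells with at least 1 eGFP UMI were compared with the rest among wound fibroblast-class cells with the library as a block, and an interaction term compared that difference between wound and uninjured skin. Those sums are splits of the same libraries, so their standard errors measure only how the splits vary. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. The estimated version has 1 residual degree of freedom, so a list could hardly pass it after adjustment. Its adjusted p is given without a conclusion. Many lists outside the wound comparison of fibroblasts carry only this p, which does not mean that they failed the preset test. The number of lists that passed the preset test in each comparison is given in the section on processing. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. A fold against a library at 0 counts is a bound from a floor of 3 counts per library, on the same normalized scale as the CPM. Alternatives without a test gave no fold for a gene with at most 3 UMIs on either side, a limit applied after the values were seen.

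The 21 gene lists covered extracellular matrix, collagen processing and cross-linking, contractile and myofibroblast genes, mature adipocyte, lipolysis and fatty acid oxidation, fatty acid and triglyceride synthesis, adipocyte precursor, papillary dermis and dermal papilla, reticular dermis and hypodermis, matrix proteases and inhibitors, TGF-beta, Wnt and BMP, chemokines and cytokines, interferon response, complement, glycolysis, hypoxia, oxidative phosphorylation, the secretory pathway, cell cycle and immediate early genes. Lists, markers and the rule for named genes were fixed before the data were examined. That rule took the 8 genes with the largest change in each direction with a mean of at least 20 CPM, up to 3 members of each list by p, and 14 genes named in every comparison where they were tested. From the list members, the 2 largest by size are given for fibroblasts, 1 for the reporter comparison and 0 elsewhere, to save space. In keratinocytes, 1 gene that the rule takes is not reported here.

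Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, cells with at most 10% mitochondrial UMIs, equal cell numbers thinned to 3000 UMIs per cell, own clusters (leidenalg 0.10.2 with 2000 variable genes and 30 components), eGFP-negative cells only, at least 2 eGFP UMIs, no library block, and each wound library left out. Chosen after seeing the data were cluster 3 left out or kept, uninjured cluster 3 cells left out of the keratinocytes, cluster 10 added, the unnamed own cluster 11 added, a rule on markers per cell, a split by sex genes, values within clusters, and matching of eGFP-negative cells on cluster and UMIs. A cell was called XX with at least 1 Xist UMI and at most 1 Y-linked UMI (Ddx3y, Uty, Eif2s3y and Kdm5d), XY with Y-linked UMIs and no Xist UMI, and both with at least 1 Xist UMI and at least 2 Y-linked UMIs. These limits, and a limit of 15 eGFP UMIs used in the closing section, were set after looking at the counts.

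The fits were tested on simulated data with 200 changed genes of at least 20 CPM. All simulated genes had at least 20 CPM and shared the common dispersion of the fit. Real genes vary in dispersion, so the percentages found may be higher than in the data. In fibroblast-class sums, 93% of genes changed 2-fold and 100% of genes changed 4-fold were found. In keratinocytes these were 14% and 80%, and in immune cells 18% and 95%, so smaller differences in those classes were mostly not detectable. In pericytes or smooth muscle cells 87% and 99% were found, and in all cells 78% and 100%. For the reporter comparison and the interaction, 100% were found at both sizes.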

Results

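Skin cells of 3 libraries were profiled by droplet RNA-seq, 2 from day 5 wound beds and 1 from uninjured skin of mice carrying the adiponectin Cre reporter. The comparisons ask how stromal and other skin cells differ between wounded and uninjured skin, and how cells carrying the eGFP mark differ from unmarked cells. The wound library labelled female held 9827 cells and 195545246 UMIs, the wound library labelled male 14290 cells and 239423921 UMIs, and the uninjured library, labelled male, 6898 cells and 96493186 UMIs. Median UMIs per cell were 19517, 16047.5 and 12999 in that order, and median percentages of mitochondrial UMIs were 1.75, 1.73 and 2.78. The sex genes went against a label. Of the cells of the wound library labelled male, 87.0% carried Xist, the transcript expressed from the inactive X chromosome, with at most 1 Y-linked UMI, and the library labelled female held both XX and XY cells. The labels are therefore used only as names.

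Fibroblast-class cells of the wound beds carried more Tnc, Acta2 and Nos2 transcripts than those of uninjured skin, and fewer of Myoc, Sostdc1 and Inmt. Tnc, which encodes the matrix glycoprotein tenascin C, stood at 1560 ± 154 CPM in the wound libraries (SD, n = 2) and at 16.8 CPM in the uninjured library. Acta2, the smooth muscle actin of myofibroblasts, stood at 762 ± 98.9 CPM against 46.8 CPM, and Myoc, which encodes the secreted protein myocilin, at 8.89 ± 4.60 CPM against 748 CPM. The edgeR quasi-likelihood test called 6649 genes higher and 5611 lower in the wound libraries of 29859 tested. The DESeq2 Wald test, which calls 65.2% of its changed genes higher against 54.2% here, gave 5166 and 2760. Class members came mostly from clusters 0 to 5 in the wound libraries and from clusters 0, 2, 6 and 7 in the uninjured library.

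Among genes with a mean of at least 20 CPM, with predicted genes named Gm or Rik passed over, the largest increases were in Nos2, the inducible nitric oxide synthase (log2 fold change 8.49 ± 0.95 SE, adjusted p = 0.00235), Cxcl5, a neutrophil-attracting chemokine (8.09 ± 0.49), and Serpinb2, a plasminogen activator inhibitor (7.75 ± 0.92). They were followed by Xist (7.47 ± 0.81), which follows the sex of the mice, and by the imprinted noncoding RNA H19 (7.27 ± 0.24), the growth factor gene Ereg (6.72 ± 0.49), Tnc (6.54 ± 0.18) and the acute-phase gene Saa3 (6.31 ± 0.59). The largest decreases were in Myoc (-6.40 ± 0.45, adjusted p = 6.6e-04), the oestrogen sulfotransferase gene Sult1e1 (-5.81 ± 1.59, adjusted p = 0.0363) and Sostdc1, a secreted antagonist of BMP and Wnt signals (-5.81 ± 0.13). Inmt (-5.59 ± 0.41), the sphingomyelinase gene Smpd3 (-5.43 ± 0.12), the complement gene C7 (-4.91 ± 1.11), the growth factor gene Bmp4 (-4.70 ± 0.34) and Galnt15 (-4.20 ± 0.33) also fell. Col1a1 (2.19 ± 0.19), Col3a1 (2.22 ± 0.19) and Postn (2.95 ± 0.13), which encode matrix proteins, rose, as did Fabp4 (2.06 ± 0.15), a fatty acid binding protein gene of adipocytes and endothelium. In these libraries Fabp4 was far higher in pericytes or smooth muscle cells, at 1940, 2019 and 2320 CPM. Fibroblast-class cells held 41.2, 35.9 and 9.83 CPM, in the order wound labelled female, wound labelled male and uninjured. Adipoq, which encodes adiponectin, fell (-1.58 ± 0.43, adjusted p = 0.0367) on 15, 16 and 17 UMIs in the 3 libraries. It did not pass with the DESeq2 Wald test, with own clusters, with at most 10% mitochondrial UMIs or with cluster 10 added, and stood at 0.98 by the rule on markers per cell (adjusted p = 0.548). Within each cluster it had too few UMIs for a fold. Pparg (-1.77), Cd9 (-1.50), Dpp4 (-1.42), Cd34 (-0.70) and Ly6a (-0.47), genes used to mark precursor populations, also fell, while Plin1 (-0.41, adjusted p = 0.104) and Pdgfra (-0.26, adjusted p = 0.0928) did not pass. With own clusters Dpp4, Cd34, Ly6a and Sult1e1 did not pass. Own cluster 11, led by Smpd3 and Sult1e1, stayed unnamed there and held 1195 uninjured cells and 19 and 3 cells of the wound libraries labelled female and male; with it added to the class, these 4 genes passed and Adipoq did not. Ly6a also did not pass in eGFP-negative cells alone or with cluster 3 left out or kept. Within clusters 0 (0.38) and 6 (0.91) Ly6a was higher in wound cells, as Cd34 was within cluster 6 (0.91). Sult1e1 held 605 UMIs in the wound library labelled female and 4 in the one labelled male, and its log2 fold change was -12.33 without the former and -4.77 without the latter. Without the library labelled female, Nos2 stood at 7.69, Serpinb2 at 6.75, below H19 at 7.44, Saa3 at 5.67, Myoc at -7.05, Inmt at -6.22 and C7 at -7.25. Without the one labelled male, Serpinb2 stood at 8.34, Xist at 6.64 and C7 at -4.05. In each wound library alone against the uninjured one, the named genes kept their direction. Sult1e1 and C7 did not pass with the DESeq2 Wald test or in eGFP-negative cells alone.

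**Figure D1:**
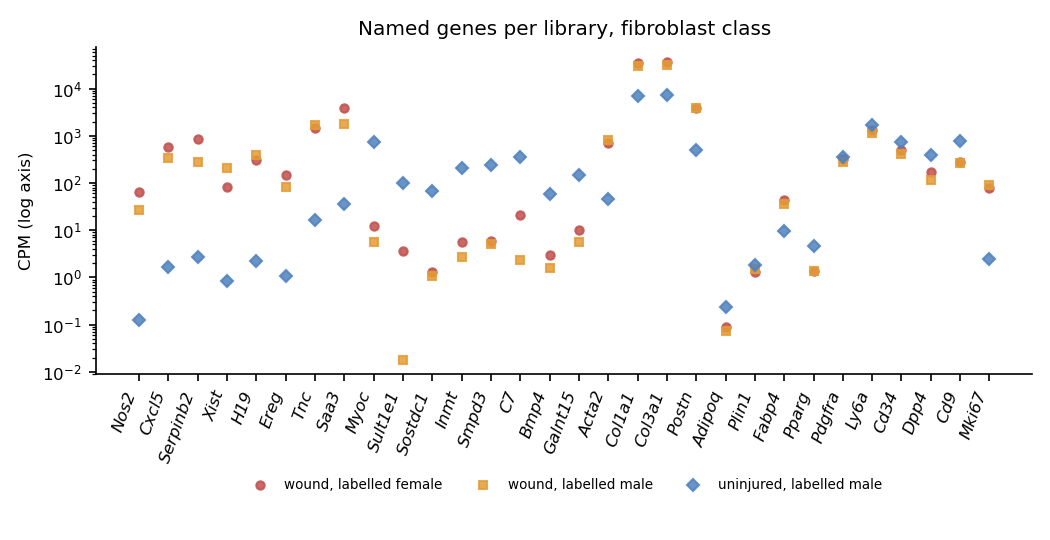
Expression of genes named for the fibroblast class, in CPM per library on a logarithmic axis, with 1 point for each of the 3 libraries. Tnc lies at 1560 CPM as the mean of the wound libraries and at 16.8 CPM in uninjured skin, and Myoc at 8.89 and 748 CPM.

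Matrix and contractile lists rose in wound fibroblast-class cells. Of 30 extracellular matrix genes, 25 rose and 2 fell, the same counts as when adjusted over the list alone (median log2 fold change 1.42, camera adjusted p = 4.3e-11, and adjusted p = 0.548 with an estimated correlation). Col12a1, a fibril-associated collagen gene, rose by 4.20. Of 21 genes of collagen processing and cross-linking, 19 rose and 1 fell, again with the same counts adjusted over the list alone, and P4ha3 (4.36) and Plod2 (3.29), which encode collagen hydroxylases, were among them (median 1.54, adjusted p = 4.3e-11, and 0.548 with an estimated correlation). Of 25 contractile genes, 22 rose and 0 fell (23 and 0 adjusted over the list alone), among them Acta2 (4.03 ± 0.17) and the actin cross-linker gene Actn1 (2.73), with a median of 1.37 and adjusted p = 1.65e-12, or 0.548 with an estimated correlation. Of 12 pericyte and smooth muscle markers, none of them in the contractile list, 8 rose and 2 fell (adjusted p = 0.0293, and 0.722 with an estimated correlation). How far pericyte or smooth muscle RNA adds to the contractile values of these sums was not tested.

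Proteases, chemokines and interferon genes rose as well. Of 23 matrix proteases and inhibitors, 15 rose and 6 fell (15 and 7 adjusted over the list alone), with Mmp10 (6.84) and Mmp9 (5.67) among them; the adjusted p was 0.00374, and 0.548 with an estimated correlation. Of 29 chemokine and cytokine genes, 20 rose and 4 fell (20 and 5 adjusted over the list alone), among them Spp1 (4.67), which encodes osteopontin, and the hepatocyte growth factor gene Hgf (2.50); the adjusted p was 1.9e-04, and 0.548 with an estimated correlation. Of 20 interferon response genes, 12 rose and 3 fell by either adjustment, that over all genes and that adjusted over the list alone, with Rsad2 (2.57) and Gbp3 (1.31) among them; the adjusted p was 6.9e-04, and 0.548 with an estimated correlation. Of 19 TGF-beta ligands and targets, 11 rose and 3 fell (13 and 3 adjusted over the list alone), with Cthrc1 (5.08) and Ltbp2 (2.59) among them; the adjusted p was 0.00102, and 0.548 with an estimated correlation. Of 17 macrophage and dendritic cell markers measured in the same sums, 6 rose and 1 fell (adjusted p = 0.0391, and 0.722 with an estimated correlation), Lyz2 by 1.55 and C1qa by 1.17.

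The glycolysis, hypoxia, oxidative phosphorylation and secretory pathway lists rose. Of 18 glycolysis genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with the lactate exporter gene Slc16a3 (4.24) and Pgk1 (2.39) among them (adjusted p = 3.42e-08, and 0.548 with an estimated correlation). Of 15 hypoxia genes, 10 rose and 0 fell (10 and 1 adjusted over the list alone), with Pdk1 (2.37) and the glucose transporter gene Slc2a1 (2.11) among them (adjusted p = 1.9e-04, and 0.561 with an estimated correlation). Of 25 oxidative phosphorylation genes, 15 rose and 0 fell by either adjustment, by less, as in Cox5a (0.90) and Atp5a1 (0.67) (adjusted p = 1.6e-04, and 0.548 with an estimated correlation). Of 19 genes of the secretory pathway, 12 rose and 2 fell (13 and 2 adjusted over the list alone), among them Kdelr3 (2.16) and P4hb (1.63) (adjusted p = 4.26e-05, and 0.548 with an estimated correlation).

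Of 28 cell cycle genes, 27 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 2.85 and adjusted p = 9.9e-16, or 0.548 with an estimated correlation. Mki67, a proliferation marker, rose by 5.10 ± 0.15 and the centromere gene Cenpa by 4.28. The size of this rise depended on cluster 3, which counted as fibroblast in the wound libraries and as keratinocyte in the uninjured one. With the 228 uninjured cells of cluster 3 kept in the class, 10 of the genes rose and 3 fell, the median was 0.17, the adjusted p was 0.116 and Mki67 stood at 0.07, not past the threshold; with cluster 3 left out of every library, 23 rose and 0 fell, with a median of 1.18.

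The mature adipocyte, precursor, papillary dermis, Wnt and BMP, and complement lists fell. Of 23 mature adipocyte genes, 3 rose and 13 fell (3 and 15 adjusted over the list alone), among them the transcription factor gene Cebpa (-1.97) and the carbonic anhydrase gene Car3 (-3.75), with a median of -1.18 and adjusted p = 1e-04, or 0.548 with an estimated correlation. Of 8 adipocyte markers, all of them members of that list, 0 rose and 3 fell (adjusted p = 0.0138, and 0.722 with an estimated correlation). The marker set is thus no separate evidence. Car3, in both sets, is also among the leading genes of cluster 15, which was named skeletal muscle. Of 18 adipocyte precursor genes, 1 rose and 12 fell by either adjustment, Cd24a at -3.71 and Anxa3 at -2.00 (median -1.12, adjusted p = 4.09e-05, and 0.548 with an estimated correlation). Of 18 genes of papillary dermis and dermal papilla, 3 rose and 13 fell (3 and 14 adjusted over the list alone), among them the Wnt effector gene Lef1 (-3.97) and the Wnt agonist gene Rspo3 (-2.62), with a median of -2.12; the adjusted p was 8.12e-06, and 0.548 with an estimated correlation. Of 28 Wnt and BMP genes, 5 rose and 20 fell (5 and 21 adjusted over the list alone), among them Bmp4 and Rspo1 (-4.39), with a median of -1.34; the adjusted p was 8.98e-06, and 0.548 with an estimated correlation. Of 13 complement genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone), among them C1qtnf1 (-1.17) and the complement regulator gene Cd55 (-1.72); the adjusted p was 0.00376, and 0.548 with an estimated correlation. Cd55 did not pass with own clusters, but did with own cluster 11 added. Wif1, Corin and Rspo3, members of the papillary list, are among the leading genes of cluster 6. Cluster 6 made up 3.70% and 4.39% of the fibroblast class in the wound libraries labelled female and male and 15.1% in the uninjured one. How far this shift sets the falls of the papillary and the Wnt and BMP lists was not tested. Within the clusters, values only, Cd55 was also higher in the wound cells of cluster 2, Rspo3 was higher in the wound cells of clusters 1, 2, 5 and 9, and Car3, Cd55 and C1qtnf1 were higher in those of cluster 6.

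The other 4 lists did not pass as sets. Of 16 reticular dermis and hypodermis genes, 5 rose and 9 fell (5 and 10 adjusted over the list alone, adjusted p = 0.077), with Gsn, which encodes the actin-severing protein gelsolin, at -4.10 and Ly6c1 at -1.38. Of 18 immediate early and dissociation stress genes, 2 rose and 9 fell by either adjustment (adjusted p = 0.0584), with Ier3 at 1.42 and Junb at -1.20. Of 23 lipolysis and fatty acid oxidation genes, 8 rose, as Cpt1a (0.98) and Acads (0.96) did, and 7 fell (9 and 8 adjusted over the list alone); the median was 0.02, the mean -0.10 and the direction of the test up (adjusted p = 0.625). Of 17 genes of fatty acid and triglyceride synthesis, 5 rose, with Me1 at 2.22, and 6 fell, with Acacb at -1.92 (5 and 7 adjusted over the list alone); the median was 0.18, the mean -0.07 and the direction up (adjusted p = 0.894).

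Markers of other cell types in the same fibroblast-class sums moved with the groups. Of 16 keratinocyte markers, 0 rose and 12 fell (0 and 13 adjusted over the list alone), Krt5 at -2.09 and Krt14 at -1.63 (adjusted p = 1.97e-05, and 0.722 with an estimated correlation). Of 6 erythroid markers, 0 rose and 3 fell, Hbb-bs at -3.17 and Hba-a1 at -3.51 (adjusted p = 0.0293, and 0.722 with an estimated correlation). Of 10 skeletal muscle markers, 1 rose and 7 fell, Acta1 at -1.03 (adjusted p = 0.0293), and of 12 Schwann cell markers, 1 rose and 4 fell (adjusted p = 0.0439), both with adjusted p = 0.722 with an estimated correlation. Of 12 fibroblast markers, 8 rose and 2 fell (adjusted p = 0.0113, and 0.722 with an estimated correlation). The sets for endothelial (3 rose, 2 fell of 11, adjusted p = 0.475), lymphatic endothelial (1 and 3 of 6, 0.416), melanocyte (2 and 2 of 7, 0.671), neutrophil (1 and 2 of 8, 0.632), T and NK (5 and 1 of 9, 0.365) and mast cells (1 and 0 of 6, 0.388) did not pass. The melanocyte median was -0.02 and the mean 0.28, and the neutrophil median was 0.07 with the direction of the test down.

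**Figure D2:**
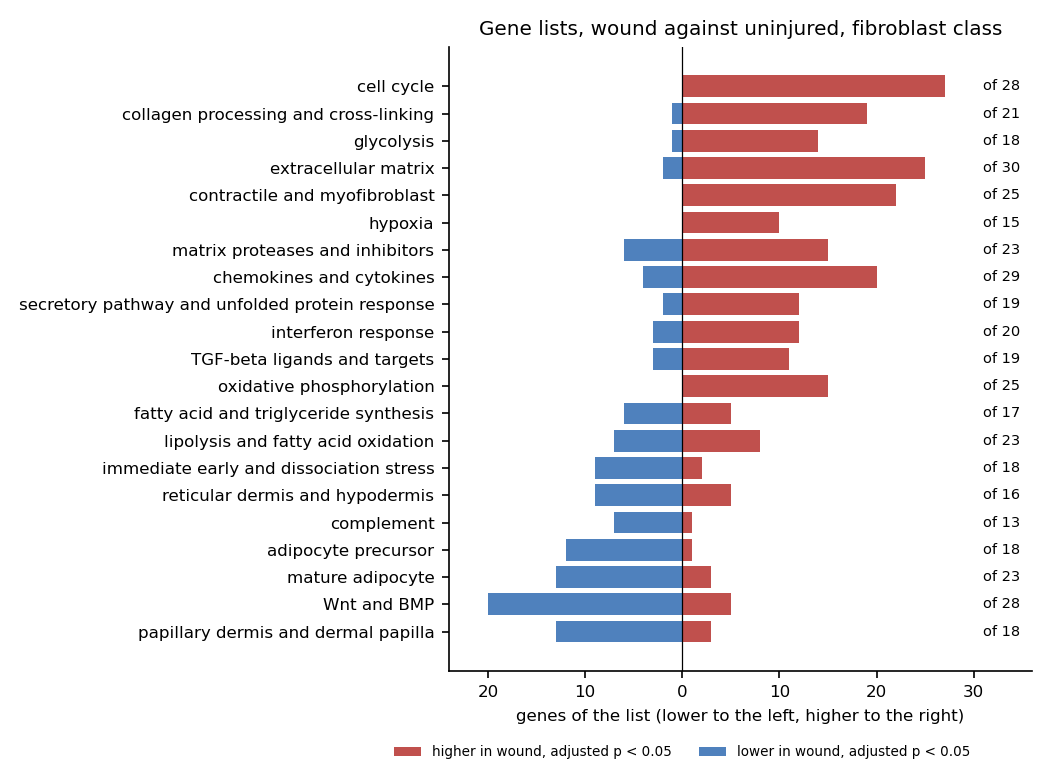
Members of the 21 fixed gene lists that rose (bars to the right) or fell (bars to the left) in wound against uninjured fibroblast-class cells, in numbers of genes, with the number tested at the right edge. In the cell cycle list 27 of 28 genes rose, and in the Wnt and BMP list 20 of 28 fell.

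The sort set which cells could enter the libraries, so shares of cells are given as measured. Fibroblast-class cells made up 86.6% of the wound library labelled female, 86.4% of the one labelled male and 73.7% of the uninjured library, with exact 95% intervals of 85.9 to 87.3%, 85.9 to 87.0% and 72.6 to 74.7%. Keratinocytes made up 2.35%, 2.97% and 13.5%, pericytes or smooth muscle cells 3.86%, 2.97% and 3.31%, immune cells 2.24%, 1.85% and 0.870%, and skeletal muscle cells 0.458%, 0.336% and 0.928%. The unnamed clusters held 4.47%, 5.43% and 7.76%. Own clusters placed 61.4% of the uninjured cells in the fibroblast class and left 17.5% unnamed, nearly all of them the 1195 cells of own cluster 11.

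With all cells of a library summed, and by the same rule, Nos2 and Cxcl5 again had the largest increases, Cstdc5 and Reg1 stood among the first 8 where Serpinb2 and Ereg had been, and Krt15 and Krt75 were among the genes that fell. Cxcl5 rose by 8.23 ± 0.53, Nos2 by 8.53 ± 0.98, Cstdc5, a stefin family gene, by 7.17 ± 0.19, Reg1 by 6.42 and H19 by 5.88, with Xist at 7.32, Saa3 at 6.64 and Tnc at 6.11. Krt15, a keratin gene of basal hair follicle cells, fell (-3.77 ± 0.10), as did Krt75 (-3.85), Myoc (-5.93), Inmt (-5.11), Smpd3 (-4.92), C7 (-4.47), Sostdc1 (-4.03) and Galnt15 (-3.72). Acta2 (2.73), Col1a1 (1.92), Col3a1 (2.41) and Postn (3.36) rose, and Pparg (-1.45), Cd9 (-1.34) and Dpp4 (-0.96) fell. Fabp4 (0.29, adjusted p = 0.232), Pdgfra (0.20, 0.180), Ly6a (-0.02, 0.896), Cd34 (-0.29, 0.159), Mki67 (0.37, 0.0580), Plin1 (-0.37, 0.118) and Adipoq (-0.57, 0.518) did not pass. The test called 6382 genes higher and 5161 lower of 30975, and the DESeq2 Wald test 5289 and 2679, of which 66.4% were higher against 55.3% here. C7, Krt75 and Dpp4 did not pass with the DESeq2 Wald test. Without the wound library labelled female, C7 stood at -6.79, Nos2 at 7.73, Saa3 at 6.03, Myoc at -6.57, Inmt at -5.73 and Krt75 at -3.11. Without the one labelled male, C7 stood at -3.61, Xist at 6.48 and Krt75 at -5.49.

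In these sums of all cells, 25 of 30 extracellular matrix genes rose and 1 fell, and 17 of 20 interferon response genes rose and 1 fell (17 and 2 adjusted over the list alone), both with adjusted p = 0.536 with an estimated correlation. Of 18 papillary dermis genes 13 fell and 3 rose (14 and 3 adjusted over the list alone), and of 28 Wnt and BMP genes 20 fell and 5 rose, again with adjusted p = 0.536 with an estimated correlation for both. Of 18 glycolysis genes 16 rose and 0 fell, and of 23 mature adipocyte genes 0 rose and 12 fell (0 and 13 adjusted over the list alone), both with adjusted p = 0.621 with an estimated correlation. Of 28 cell cycle genes 8 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 0.00327, and 0.769 with an estimated correlation). Of 16 keratinocyte markers 13 fell, of 7 mast cell markers 5, of 12 Schwann cell markers 8 and of 6 erythroid markers 4, while 9 of 12 fibroblast markers rose; each of these 5 sets had adjusted p = 0.875 with an estimated correlation.

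Keratinocytes of the wound libraries carried Krt6b, Cstdc5 and Mmp13 transcripts that were scarce in uninjured keratinocytes. Krt6b, a keratin gene of activated epidermis, stood at 411 ± 154 CPM (SD, n = 2) against 0.210 CPM and rose by 10.85 ± 0.61. Cstdc5 rose by 10.22 ± 0.32 and Stfa1, a stefin gene, by 9.26 ± 0.38. Sprr2g, a small proline-rich protein gene, had 0 UMIs in the uninjured library and was at least 142-fold higher, and Sprr1b (7.94) and Mmp13 (8.23) also rose. Mmp9 rose to 12.2 and 52.3 CPM in the wound libraries labelled female and male and AL603804.1 to 36.9 and 30.3 CPM, from 2 uninjured UMIs each, too few for a fold. Lor, which encodes the envelope protein loricrin, fell by 4.97 ± 0.21, and so did Cidea (-3.56), the fatty acid elongase gene Elovl6 (-3.26), the desaturase gene Scd1 (-2.33), Cers4 (-2.00) and Mgll (-1.57), along with Rarres1 (-2.18).

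The test called 353 genes higher and 66 lower in keratinocytes of 16271, and 1233 and 477 with no filter on low counts. Of 17 fatty acid and triglyceride synthesis genes 0 rose and 4 fell (0 and 7 adjusted over the list alone), and 5 of 19 interferon response genes rose and 0 fell (14 and 0 adjusted over the list alone), both with adjusted p = 0.43 with an estimated correlation. Of 23 matrix proteases and inhibitors 10 rose and 0 fell (14 and 0 adjusted over the list alone), and of 30 extracellular matrix genes 17 rose and 0 fell (27 and 0 adjusted over the list alone), again with adjusted p = 0.43 with an estimated correlation for both. Fibroblast markers moved with them, 6 of 12 higher and 0 lower (adjusted p = 0.696 with an estimated correlation). Col1a1 (2.40), Col3a1 (3.09), Postn (2.99) and Ly6a (1.52) rose. Whether fibroblast RNA or mixed droplets carried these transcripts was not tested. The direction of the cell cycle list depended on the 228 uninjured cells of cluster 3, which were counted as keratinocytes. With them, the list was lower as a set (median -0.44, adjusted p = 4.34e-11, and 0.43 with an estimated correlation), with 0 of 28 genes past the threshold (0 and 5 adjusted over the list alone). Without them, it was higher (median 1.24, adjusted p = 5.85e-14, and 0.428 with an estimated correlation), 14 genes rose and 0 fell (16 and 0 adjusted over the list alone), and Mki67 rose by 1.499 (adjusted p = 0.0164). Of 16 keratinocyte markers 3 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 9.5e-05, and 0.696 with an estimated correlation), but without those cells 2 rose and 2 fell and the set did not pass (adjusted p = 0.136). Acta2 (1.18), Mki67 (-0.57), Fabp4 (-1.07), Pparg (-1.77), Plin1 (-0.66), Pdgfra (0.65), Cd34 (0.30), Dpp4 (0.25) and Cd9 (-0.03) did not pass.

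Pericytes or smooth muscle cells of the wound libraries carried more cell cycle and matrix transcripts than those of uninjured skin. In the wound libraries labelled female and male, Postn stood at 1221 and 1522 CPM in these cells. It stood at 877 and 1648 CPM in immune cells and at 3596 and 4014 CPM in fibroblast-class cells. How far fibroblast RNA or mixed droplets carried the matrix transcripts was not tested. All 28 cell cycle genes rose, also when adjusted over the list alone, with Mki67 at 2.79 ± 0.28 (adjusted p = 0.585 with an estimated correlation for the list). Of 30 extracellular matrix genes 22 rose and 2 fell (23 and 2 adjusted over the list alone), of 21 collagen processing genes 18 rose and 0 fell (19 and 0 adjusted over the list alone), and of 19 secretory pathway genes 14 rose and 1 fell (15 and 1 adjusted over the list alone), each with adjusted p = 0.585 with an estimated correlation. Of 15 mature adipocyte genes 0 rose and 8 fell, and of 12 complement genes 0 rose and 5 fell (0 and 6 adjusted over the list alone), both again with adjusted p = 0.585 with an estimated correlation. Of 25 contractile genes 10 rose and 6 fell (adjusted p = 0.24), and Acta2 stood at 0.13 (adjusted p = 0.447).

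By size, Cxcl3, a chemokine gene with 0 uninjured UMIs, was at least 24.5-fold higher in these cells. Cthrc1, which encodes a secreted collagen triple helix repeat protein, stood at 226 ± 37.5 CPM in the wound libraries (SD, n = 2) against 1.82 CPM, which was 3 UMIs. Cxcl5, Ptprn and Cd276 also rose, to means of 58.2, 49.6 and 45.4 CPM, and Hp and Il11 to 145 and 131 UMIs in the wound library labelled female, from 1 uninjured UMI each, or 2 for Cxcl5, too few for a fold. Saa3 rose by 6.09 ± 0.22. Myoc fell (-6.00 ± 0.44, on 16 and 2 UMIs in the wound libraries labelled female and male, and -5.16 without the latter), with the apolipoprotein gene Apod at -4.18 and the phospholamban gene Pln at -4.01, followed by Adgrg6 (-3.90), Timp4 (-3.81), Scn4b (-3.60), Hmcn2 (-3.40) and Pcolce2 (-3.22). Col1a1 (1.54), Col3a1 (1.45) and Postn (2.31) rose, and Pparg (-1.27), Dpp4 (-1.36) and Ly6a (-0.36, lost with no filter on low counts) fell, while Fabp4 (-0.22), Plin1 (0.13), Pdgfra (-0.07), Cd34 (-0.34) and Cd9 (-0.25) did not pass. The test called 1963 genes higher and 1364 lower of 14993. Of 12 fibroblast markers 7 rose and 1 fell (adjusted p = 0.925 with an estimated correlation), and the median mitochondrial share was 8.05% in the 228 uninjured cells against 3.31% and 3.25% in the wound libraries.

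Mast cell genes were among the genes that fell in the immune class. Besides macrophage or dendritic markers, neutrophil markers met the naming limits in every library, but mast and T or NK markers only in uninjured cells. The class comparison thus spans different mixes of immune cell types. Mcpt4, a mast cell protease gene, had 984 UMIs in the 60 uninjured immune cells and 0 in both wound libraries, and was at least 1040.4-fold lower there. Cpa3, the mast cell carboxypeptidase gene, stood at 1244 CPM against 0.570 CPM as the wound mean, and Cma1 and Tpsb2, further mast cell protease genes, had 433 and 388 uninjured UMIs against 1 in both wound libraries together. Mrgprb1, a mast cell receptor gene, stood at 85.2 CPM against 0.570, Krt15 at 179.8 against 0.597, and Gjb2 and Il13, with 0 wound UMIs, were at least 64.5-fold and 49.7-fold lower. All 6 mast cell markers tested fell, and 7 of 10 keratinocyte markers fell (both with adjusted p = 0.602 with an estimated correlation).

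In the other direction, Cthrc1 was at least 49.7-fold higher in the wound immune class, Serpinb2 at least 15.4-fold, the tenascin gene Tnn 13.7-fold, H19 12.3-fold, Adam12 10.9-fold, Fbn2 8.09-fold, Chl1 5.57-fold and Ppbp, a platelet chemokine gene, 4.96-fold, each with 0 uninjured UMIs. Ppbp did not pass with DESeq2 size factors (adjusted p = 0.0621). Acta2 stood at 270 CPM against 5.68 CPM, on 3 uninjured UMIs, and Postn (5.30), Col3a1 (2.48) and Col1a1 (1.49) rose. Of 12 fibroblast markers 6 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 0.699 with an estimated correlation). Of 29 extracellular matrix genes 20 rose and 0 fell (23 and 0 adjusted over the list alone), and of 18 immediate early genes 0 rose and 8 fell (1 and 16 adjusted over the list alone), both with adjusted p = 0.581 with an estimated correlation. Mki67 fell by 1.47, and Fabp4 (2.03), Pdgfra (2.66), Ly6a (1.10), Cd34 (0.55), Dpp4 (0.40), Pparg (-0.87) and Cd9 (-0.47) did not pass. The test called 286 genes higher and 282 lower of 11288. With 60 uninjured cells left by a sort against CD45, the class holds what passed that sort. Whether fibroblast RNA or mixed droplets carried the matrix and fibroblast transcripts of this class was not tested.

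Cells with at least 1 eGFP UMI occurred in every class. Among fibroblast-class cells they made up 21.0% (exact 95% interval 20.2 to 21.9%) and 20.2% (19.5 to 20.9%) of the wound libraries labelled female and male and 22.0% (20.9 to 23.2%) of the uninjured library, at median depths of 20522, 16864 and 13054 UMIs. In keratinocytes, which do not derive from adipocytes, the shares were 32.5%, 20.9% and 31.9% at 13891, 10823 and 17121 UMIs, and the fibroblast shares lay at or below them. In pericytes or smooth muscle cells they were 21.9% (83 of 379), 85 of 425 cells and 13.6% (31 of 228), and in immune cells 11.8%, 9.06% and 26.7% at 5376.5, 4527 and 8002.5 UMIs. In skeletal muscle cells they were lower, at 6.67%, 4.17% and 12.5%, on 3, 2 and 8 cells with an eGFP UMI and at 8380, 8218.5 and 6397.5 UMIs, and eGFP stood there at 4.85, 5.24 and 26.1 CPM against 17.1, 16.9 and 27.4 CPM in fibroblast-class cells. The share as counted thus differed between classes that should lack the mark, and no share of recombined fibroblasts is read from these values. Thinned to 3000 UMIs per cell, with no cell left out, the fibroblast shares were 4.48%, 4.96% and 6.89% and the keratinocyte shares 9.96%, 6.59% and 7.85%. Among reporter UMIs, eGFP made up 34.1%, 33.3% and 37.3% in fibroblast-class cells and 21.8%, 21.9% and 20.5% in keratinocytes.

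**Figure D3:**
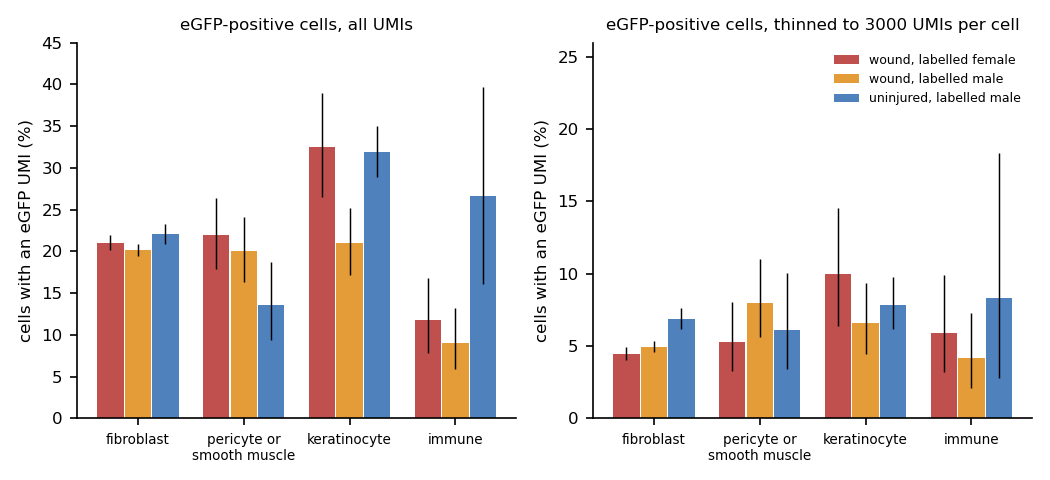
Share of cells with at least 1 eGFP UMI by cell class and library, in percent of cells, with exact 95% intervals, as counted and after thinning each cell to 3000 UMIs. Fibroblast-class shares lie at 21.0%, 20.2% and 22.0% as counted and at 4.48%, 4.96% and 6.89% thinned.

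Among wound fibroblast-class cells, those with an eGFP UMI carried more cell cycle and contractile transcripts and fewer of reticular dermis, precursor and complement genes than the rest. The histone genes Hist1h2ae (log2 difference 1.37 ± 0.03 SE), Hist1h1b (1.35), Hist1h2ap (1.30), Hist1h4d (0.93) and Hist1h1e (0.93) and the mitotic genes Top2a (1.03), Kif11 (1.02) and Ube2c (0.99) were higher. Cxcl13, a B cell chemokine gene (-1.51 ± 0.05), Reg1 (-1.48), the ferritin receptor gene Scara5 (-1.22), Ntrk2 (-1.19), C3 (-1.18), the adventitial fibroblast marker Pi16 (-1.16), Entpd2 (-1.09) and Selenop (-1.06) were lower. The test, on 2 libraries each split in 2, called 2597 genes higher and 2948 lower of 25863, but 21 and 20 with no library block, 304 and 389 with all 3 libraries in 1 fit, and 253 and 384 against eGFP-negative cells matched on cluster and UMIs. In the wound libraries labelled female and male, eGFP-positive cells made up 35.2% and 33.2% of cluster 3, at median depths of 27341 and 23350 UMIs, and 12.0% and 10.8% of cluster 0, at 19111 and 15193 UMIs. The groups compared thus differed in cluster make-up and depth before matching. The sums are splits of the same libraries, so these errors do not measure the spread between mice.

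All 28 cell cycle genes were higher in eGFP-positive cells (median 0.75, Mki67 0.87, adjusted p = 0.304 with an estimated correlation), and in matched cells 8 were higher and 1 lower (14 and 3 adjusted over the list alone), with a median of 0.09. Of 25 contractile genes 22 were higher and 2 lower, and 5 and 0 in matched cells (adjusted p = 0.304 with an estimated correlation before matching), with Acta2 at 0.54 and Tagln at 0.56. Of 16 reticular dermis genes 0 were higher and 16 lower, with the Wnt antagonist gene Sfrp4 at -0.98, and 0 and 10 in matched cells (0 and 13 adjusted over the list alone). Of 18 precursor genes 0 were higher and 16 lower, and 0 and 9 in matched cells. Both lists had adjusted p = 0.304 with an estimated correlation before matching. Of 13 complement genes 1 was higher and 11 lower, and in matched cells 0 and 7 of 12 (0 and 9 adjusted over the list alone). Of 20 interferon response genes 1 was higher and 17 lower (2 and 18 adjusted over the list alone), with Ifit3 at -0.93. Both had adjusted p = 0.304 with an estimated correlation before matching. Of 18 glycolysis genes 14 were higher and 1 lower, with Slc16a3 at 0.44 (adjusted p = 0.304 with an estimated correlation). Of 12 fibroblast markers 0 were higher and 9 lower, and of 6 erythroid markers 0 were higher and 4 lower (both adjusted p = 0.622 with an estimated correlation).

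Of 30 extracellular matrix genes 3 were higher and 18 lower (4 and 21 adjusted over the list alone), with Col14a1 at -0.57, and of 23 proteases and inhibitors 3 were higher and 14 lower, with Mmp3 at -0.78 (both adjusted p = 0.304 with an estimated correlation). Of 29 chemokine and cytokine genes 6 were higher and 20 lower (6 and 21 adjusted over the list alone), with the eotaxin gene Ccl11 at -0.85 (adjusted p = 0.392 with an estimated correlation). Of 20 mature adipocyte genes 3 were higher and 7 lower (3 and 8 adjusted over the list alone), with the fatty acid transporter gene Cd36 at -1.21, and of 23 lipolysis genes 0 were higher and 8 lower (1 and 10 adjusted over the list alone), with Mgll at -0.76. Both had adjusted p = 0.392 with an estimated correlation. Of 18 immediate early genes 5 were higher and 10 lower, with Dnajb1 at -0.45, but 6 were higher and 2 lower in matched cells, where the direction of the list turned (adjusted p = 0.304 with an estimated correlation before matching and 0.231 after). Adamts2 stood at -0.32, Lpin1 at -0.55, Crabp1 at 0.48, Ltbp2 at 0.40, Adm at -0.79, Cox5a at 0.17 and Sec61b at 0.19, each past the threshold. In matched cells Ube2c, Adamts2, Lpin1, Adm, Sec61b, Col1a1 and Pparg did not pass, and Cox5a (-0.023, adjusted p = 0.841) and Cd9 (0.026, adjusted p = 0.797) turned direction without passing. With all 3 libraries in 1 fit 24 named genes lost the call, among them Acta2, Tagln, Fabp4 and Cd34, and with no library block 37 did; Cd36 did not pass with the DESeq2 Wald test, which gave Pparg no adjusted p. Fabp4 (-0.69), Pparg (-0.67), Dpp4 (-0.73), Ly6a (-0.63), Cd34 (-0.59), Col3a1 (-0.27), Pdgfra (-0.25), Cd9 (-0.14) and Col1a1 (-0.13) were lower, and Postn (0.02) and Plin1 (-0.08) did not pass. Without the wound library labelled male, Cd36 stood at -0.74 and Pparg at -0.37.

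The difference between eGFP-positive and eGFP-negative fibroblast-class cells itself differed between wound and uninjured skin, in an interaction test, for 393 genes in the positive direction and 837 in the negative of 25820. Saa3 stood at 3.85 CPM in positive and 46.5 CPM in negative uninjured cells, at 3810 and 3899 CPM in those of the wound library labelled female and at 1614 and 1895 CPM in those of the one labelled male (interaction 3.46 ± 0.17). Acta2 stood at 26.5 and 54.0 CPM in uninjured cells, and in the same order at 891 and 631 and at 1125 and 750 CPM in the wound libraries (1.57 ± 0.07). Fabp4 stood at 20.1 CPM in positive and 6.16 CPM in negative uninjured cells, and at 30.8 and 48.1 and at 23.8 and 39.5 CPM in those of the wound libraries (-2.39 ± 0.12). Hbb-bs, a haemoglobin gene of red cells, stood at 310 CPM in positive and 76.9 CPM in negative uninjured cells and at 2.77 and 5.69 and at 2.49 and 31.7 CPM in those of the wound libraries (-4.91 ± 0.29).

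Hist1h2ae (1.54), Igfbp2 (1.36), Hmmr (1.17), Hist1h1e (1.16), Cdca8 (1.15) and Tes (0.99) also had positive interactions, and Sult1e1 (-2.03), Hp (-1.94), H19 (-1.40), Ccl19 (-1.38), Ctla2a (-1.24), Inmt (-1.19) and Pparg (-1.26) negative ones. Hist1h2ae and Hmmr are among the leading genes of cluster 3, which was in the fibroblast class only in the wound libraries. Dpp4 (-0.52), Cd34 (-0.48), Ly6a (-0.43), Col3a1 (-0.36), Col1a1 (-0.35), Pdgfra (-0.26) and Cd9 (-0.14) were negative, and Mki67 (0.80), Postn (0.01), Plin1 (-0.29) and Adipoq (0.60) did not pass. Of 16 reticular dermis genes 0 had positive and 13 negative interactions (0 and 14 adjusted over the list alone), of 18 precursor genes 0 and 12 (0 and 15 adjusted over the list alone), of 30 extracellular matrix genes 2 and 14 (3 and 19 adjusted over the list alone), and of 28 cell cycle genes 8 and 0 (15 and 0 adjusted over the list alone). These 4 lists had adjusted p = 0.351 with an estimated correlation. Of 25 contractile genes 16 had positive and 0 negative interactions (20 and 1 adjusted over the list alone; adjusted p = 0.376 with an estimated correlation). Of 23 mature adipocyte genes 1 had a positive and 6 a negative interaction (2 and 8 adjusted over the list alone), with a median of -0.23, a mean of 0.03 and the direction of the test down (adjusted p = 0.47 with an estimated correlation). The uninjured side rests on 1 library. Cluster 3, with eGFP-positive shares of 35.2% and 33.2% in the wound libraries labelled female and male, was left out of the uninjured class. No interaction was fitted with cluster 3 changed or on cells matched on cluster and UMIs. How far class make-up sets the cell cycle interactions was not tested.

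Xist and Y-linked genes were compared with the sexes on the labels. In the wound library labelled male, Xist stood at 218 CPM and the Y-linked gene Ddx3y at 0.986 CPM; 87.0% of cells were called XX and 1.10% XY. In the wound library labelled female, Xist stood at 79.2 CPM and Ddx3y at 58.3 CPM; 32.4% of cells were called XX, 53.3% XY and 3.42% both. In the uninjured library, labelled male, Xist stood at 1.06 CPM and Ddx3y at 114 CPM, and 5519 of its 6898 cells were called XY. A comparison of wound with uninjured skin by sex is thus possible only for XY cells.

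**Figure D4:**
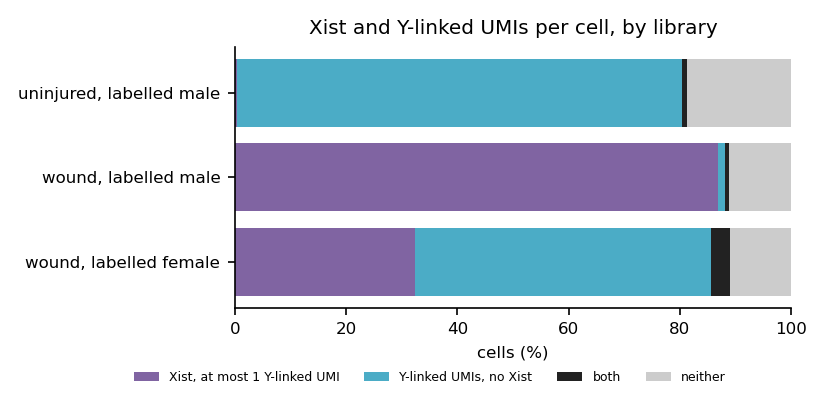
Cells of each library by Xist and Y-linked UMIs, as stacked bars in percent of the cells of that library. The wound library labelled male is 87.0% XX, the one labelled female is 32.4% XX and 53.3% XY, and 5519 of the 6898 cells of the uninjured library are XY.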

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

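The tests of depth per cell, of free RNA from 1 source and of the mixed library were chosen after the result was seen, and the reading of the adipocyte lineage test was changed after its value was seen.

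eGFP UMIs occurred in every cell class, at shares in fibroblast-class cells that were at or below those in keratinocytes. The share was 2.45 times higher in the 5216 wound fibroblast-class cells with the most UMIs than in the 5217 with the fewest, and that ratio was 0.839 after thinning, so depth may set much of the call. The eGFP share of reporter UMIs was at least 1.52 times higher in fibroblast-class cells than in keratinocytes, with intervals apart in all 3 libraries. That argues against free RNA from 1 source as the whole origin of both reporters together, but does not decide the origin of eGFP alone. In the order wound labelled female, wound labelled male and uninjured, tdTomato stood at 107, 82.8 and 102 CPM in keratinocytes. In fibroblast-class cells tdTomato stood at 33.0, 33.9 and 46.0 CPM, so the share can differ through tdTomato alone. eGFP stood at 29.8, 23.2 and 26.3 CPM in keratinocytes and at 17.1, 16.9 and 27.4 CPM in fibroblast-class cells. Free RNA as the origin of the eGFP UMIs stays open. A criterion written before the value was seen, that a mature adipocyte list lower in matched eGFP-positive cells at an adjusted p under 0.05 counts against an adipocyte lineage of these cells, was met (adjusted p = 0.00334). The reading was changed afterwards and the lineage is left open, because recombination is inherited and a marked cell need not keep adipocyte genes. The changed criterion also asked that the fall hold with an estimated correlation, where the adjusted p was 0.336. That version has 1 residual degree of freedom and passed 0 lists in every comparison. The changed criterion could thus hardly count against an adipocyte lineage, and its outcome decides nothing.

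Xist and Y-linked UMIs stood together in the wound library labelled female, and Xist stood at 218 CPM in the one labelled male while Ddx3y stood at 58.3 CPM in the one labelled female. In the library labelled female, 336 cells held Xist and at least 2 Y-linked UMIs, 0.209 of the 1606 that would hold both if the counts fell on cells independently. That value argues against free RNA carried between cells as the whole origin and is consistent with cells of XX and XY mice in 1 library. The sex on the label of the other wound library is contradicted by its cells, and whether labels were exchanged or written wrongly stays open. No biological explanation was tested.

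Of 5867 genes called in fibroblast-class cells with a log2 fold change of at least 1 either way, 99.95% kept their sign between XY wound cells and XY uninjured cells, as did 99.96% of the 4964 with more than 3 UMIs on each side, which argues against the sex of the mice as the whole cause. Of the 4126 that were tested with equal cell numbers thinned to 1 depth, 99.95% kept their sign. The thinned sums are drawn from the same cells, so large called changes could hardly turn sign in them. The part of depth and cell number is thus not decided, and calls fell to 4092 higher and 3392 lower. The median of the within-cluster change, as a share of the pooled one, was 0.733, and 36.3% of the genes had the same sign in all 8 clusters. For the 1934 genes with more than 3 UMIs on each side of every cluster these were 0.759 and 62.7%, so the make-up of clusters stays open as a partial source and cannot be told apart from change within cells. The wound itself, the mice and the library remain joined in the design, since uninjured skin is 1 library.

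The difference between eGFP-positive and eGFP-negative cells differed between wound and uninjured skin by an interaction test for 1230 genes. Among the named genes the interactions led with 3.46 for Saa3, 1.57 for Acta2 and 1.54 for Hist1h2ae, and -4.91 for Hbb-bs, -2.39 for Fabp4 and -2.03 for Sult1e1. Hist1h2ae is a leading gene of cluster 3, which was in the class only in the wound libraries. No interaction was fitted on cells matched on cluster and UMIs, so the part of class make-up was not tested.

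Outside the comparisons, 14 cells held at least 15 eGFP UMIs, up to 61, while 13 of them had no tdTomato UMI, against 57.6% of other cells as deep.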

How the results depend on the processing

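Tests within clusters, by sex, with clusters 3 or 10 or own cluster 11 changed, by markers per cell and on matched cells were chosen after the result was seen. For 258 values of named genes there were 2662 alternative values. Of these, 1939 kept their direction and side of the threshold or, with no test, moved by less than the main fit's standard error. The call was lost for 95 and gained for 12. With no test, 588 moved by more or turned direction for a gene not past the threshold. The remaining 28 reversed. A further 119 values with no test (62 within clusters, 56 leaving out a wound library and 1 in XY cells) rested on at most 3 UMIs on 1 side and gave no fold. Leaving out a wound library gives no test. Of 404 such values 273 moved by less than that standard error, and 131 moved by more or turned direction. A turned direction counted as reversed only for a gene past the threshold, and 0 did so. For other genes it counts among the 131. The widest ranges in the fibroblast class were -12.33 to -4.77 for Sult1e1 and -7.25 to -4.05 for C7. Sult1e1 and C7 lost the call with the DESeq2 Wald test and in eGFP-negative cells, and Ly6a, Cd34, Dpp4 and Cd55 with own clusters, as did Sult1e1; with own cluster 11, left unnamed there, added to the class all 5 passed. The cause was not tested unless given. No paired analysis was possible because the wound and uninjured libraries share no replicate number. A filter at 1000 UMIs removed no cell. Depth limits folds against 0 UMIs, which are bounds. In data simulated at each fit's common dispersion, 14% and 18% of 2-fold changes were found in keratinocytes and immune cells. In pericytes or smooth muscle cells 87% were found.

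With equal cell numbers thinned to 3000 UMIs, fibroblast calls fell to 4092 higher and 3392 lower; the setting lowers cell number and UMIs together, and their parts were not tested. The DESeq2 Wald test called 2760 lower in fibroblasts and 2679 in all cells. With no filter on low counts there were 1233 higher and 477 lower in keratinocytes, 791 and 512 in immune cells, and 636 positive interactions. In the reporter comparison the calls were 972 and 1245 with the DESeq2 Wald test, 21 and 20 with no replicate block, 674 and 960 thinned, 253 and 384 matched on cluster and UMIs, and 304 and 389 with all 3 libraries in 1 fit. With an estimated correlation 0 lists passed camera in each of the 7 comparisons. That version has 1 residual degree of freedom and decides nothing about the lists. With the preset correlation 17 passed for fibroblasts, 16 for all cells, 15 for keratinocytes and 13 for pericytes or smooth muscle. It passed 10 for immune cells, 18 for the reporter and 15 for the interaction. At an unadjusted p under 0.05 with an estimated correlation, 2 passed for the reporter, 1 for the interaction and 0 for the other comparisons. With at least 2 eGFP UMIs, the shares of fibroblast-class cells were 6.73%, 5.86% and 7.46%, and with at least 1 after thinning they were 4.48%, 4.96% and 6.89%, in the order wound labelled female, wound labelled male and uninjured. The fibroblast class made up 87.3% of the first and 76.4% of the third with at most 10% mitochondrial UMIs, and 89.0%, 89.0% and 61.4% with own clusters.

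Xist stood at 0 with sex as a term, which the split by Xist fixes. Within cluster 6, Plod2 stood at -0.56, Car3 at 0.26, Acads at -0.047, Acacb at 0.63, Ly6c1 at 0.65, Cd55 at 0.58, C1qtnf1 at 0.36, Pdk1 at -0.0048, Slc2a1 at -0.41, Ier3 at -0.16, Ly6a at 0.91 and Cd34 at 0.91. Within cluster 0, Acacb stood at 0.63 and Ly6a at 0.38; within cluster 1, Rspo3 at 0.36; within cluster 2, Rspo3 at 1.08 and Cd55 at 0.15; within cluster 5, Rspo3 at 2.16; within cluster 9, Rspo3 at 1.57 and Cox5a at -0.025. By markers per cell, Adipoq stood at 0.98. In keratinocytes, Mki67 stood at 1.499 without the uninjured cells of cluster 3. In all cells, Ly6a stood at 0.014 with DESeq2 size factors and 0.014 with the Wald test. In matched reporter cells, Cox5a stood at -0.023 and Cd9 at 0.026, and with at least 2 eGFP UMIs Postn stood at -0.063.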

Other observations

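The comparison of XX with XY cells of the mixed library was chosen after the sex genes were seen.

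Among fibroblast-class cells of the wound library labelled female, XX and XY cells differed by more than 1 on the log2 scale in 42 of 5982 genes, with a median size of 0.0952, and the 2 wound libraries differed by as much in 20, with a median of 0.0672. Several genes were lower in the XX cells. Serpinb2 stood at 301 CPM in XX and 1189 CPM in XY cells, the haptoglobin gene Hp at 79.3 and 466, the apolipoprotein gene Apoe at 175 and 705, the lubricin gene Prg4 at 183 and 717, the chemokine gene Cxcl14 at 94.9 and 295, the lipocalin gene Lcn2 at 27.4 and 94.4 and Dmkn at 20.5 and 154. These are sums over cells of 1 library with no replicate, and mouse, strain and sex are not separable in them; Xist and Ddx3y differ by construction of the split. These genes were named after their values were seen.

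Transcripts assigned to 3 autosomal pseudogenes also differed between XX and XY cells. Ftl2-ps, on chromosome 4 from 125504288 to 125504839 in GENCODE vM21, stood at 2.45 CPM in XX and 105 CPM in XY cells, and at 66.0, 0.720 and 97.9 CPM in the wound libraries labelled female and male and the uninjured library. Rps15a-ps8, on chromosome 4 from 53791070 to 53791456, stood at 2.11 and 95.6 CPM, and at 60.4, 0.815 and 60.8 CPM in the libraries. Ftl1-ps1, on chromosome 13 from 74399694 to 74407346, stood at 13.9 and 274 CPM, and at 177, 10.8 and 305 CPM in the libraries. Reads of these pseudogenes can be shared with their parent genes, so the values are uncertain.

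The 14 cells with at least 15 eGFP UMIs had a median of 20206 UMIs, and 7, 3 and 4 of them came from the wound library labelled female, the one labelled male and the uninjured library. The next highest cell had 14 eGFP UMIs. By class, 12 were fibroblast and 2 unnamed, Adipoq UMIs occurred in 2, Fabp4 in 8, Acta2 in 8, Pdgfra in 12 and Col1a1 in 14. Adipoq stood at 42.9 CPM on 13 UMIs and Fabp4 at 837 CPM on 254 UMIs. In the fibroblast class Adipoq stood at 0.084, 0.073 and 0.249 CPM and Fabp4 at 41.2, 35.9 and 9.83 CPM, in the same order of libraries. These levels rest on few cells, and their lineage was not tested.

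No doublet caller was run. From cells with both Xist and Y-linked UMIs in the mixed library, 5.56% of droplets would hold more than 1 cell, and cells with both had a median of 31918 UMIs against 20137 in cells called XX or XY. Between libraries, 81 cell barcodes were shared.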
